A study of Mus musculus with 2 samples.

How the data were processed

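The study compared miRNA in whole mouse embryos of the C57BL/6 strain at embryonic day E18.5, 1 wild type sample and 1 sample lacking estrogen receptor alpha (ERalpha), the nuclear hormone receptor encoded by Esr1. Per the labels' protocols, 100 µg of total RNA was separated by size on a flashPAGE gel system to enrich small RNA, labelled with an amine-reactive dye through the mirVana kit and hybridised in 1 colour (Cy5). The labels do not say whether a sample holds 1 embryo or a pool. The scanner, the image software and the background setting are not given in the sources used here.

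Each array's deposited file holds a raw intensity for 1152 spots, per the file headers, on a linear scale with arbitrary units and with no background or flag column. The spots of both arrays were listed in the same order, with 381 probe identifiers. Of these, 380 had 3 neighbouring spots and 1 had 12 spots. The authors' deposited value table holds a linear intensity for 377 probes. Comparison with the spots showed that each value is the mean of 3 raw spot intensities times 1 factor per array, 0.996 for wild type and 0.818 for knockout. What set the factors is not stated in the sources used here. After these factors, the medians over all 1152 spots were 136 on each array, and the medians of the value table were 135 for wild type and 137 for knockout. The values are not centred and not on a log scale. The 4 probes outside the value table were left out of the comparison. Their roles are not given in the sources used here.

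Raw spot intensities of the 377 probes were brought to log2 and quantile normalised between the 2 arrays, and the 3 spots of a probe were averaged. With no background column, no background was subtracted. With no flag and no named blank spot, the rule fixed for that case was used: 188 probes whose mean log2 over both arrays lay above the median of all 377 were compared. These 188 probes were not spread evenly over the order of the probes in the files, as the results give. A difference is knockout minus wild type. With 1 array per group there is no replicate and no test of genotype, and no p-value is given. An SD over the 3 spots of a probe covers technical variation within an array only, and the number of arrays limits the precision. Counts were set at a difference of at least 2-fold, 1 on the log2 scale.

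The probe identifiers come with no miRNA names in the files used here. None of the 381 identifiers matched a symbol or synonym in the RefSeq gene table of the GRCm38.p6 assembly, and none matched a member of the 17 miRNA lists fixed before the data were examined. The comparisons of these lists, the comparison of miRNAs from shared primary transcripts and the choice between several probes of a miRNA were therefore not run. The rule for naming was the 12 largest differences in each direction, the members of the lists, the 5 brightest miRNAs of each array and miRNAs detected on 1 array alone. Without names, the identifiers of 2 probes per direction are printed, those with the largest differences, and the rest are summarised. The last part of the rule was not used, since no detection call was at hand.

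The order of the probes in the files was used as a measure of position. The order was divided into 16 segments of 24 probes, each with 4 rows of 6 probes. This division was chosen after the data were examined, and the files give no coordinates. The share of the variance of the differences that lay between segments was set beside 1000 random orders of the same values. To remove position, the medians of segments and of the 6 columns within each block of 4 segments were subtracted in turn. This also takes out any overall difference between the arrays.

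Alternatives fixed before the data were examined were no scaling, median centring, scaling to the 75th percentile, loess on the mean log2 with a span of 0.4, the value table as deposited, offsets of 16 and 100, other filters on dim probes and thresholds of 1.5-fold and 3-fold. Alternatives added afterwards were the removal of position, normexp on the spot intensities with an offset of 50, subtraction of each array's lowest spot and the median of the 3 spots. The calculation was tested on simulated arrays of the knockout and wild type comparison, with 377 probes, the observed effect of position and 40 changed probes. At a simulated change of 2-fold, 90.1% of the changed probes passed the square root of that fold after quantile normalisation, as did 11.1 unchanged probes on average. After removal of position without scaling, 100% passed, with 0 unchanged probes. The simulated effect of position was built from the same segment and column medians that were then removed, so this outcome was close to fixed. It does not give the rate of false calls on the real arrays. The simulation had no unsubtracted background that compresses folds, and as many probes were raised as lowered. It does not give the share of 2-fold changes that would pass the 2-fold threshold used for the counts. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for normexp, were used.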

Results

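Small RNA from whole embryos was measured on 2 arrays, 1 for wild type and 1 for ERalpha knockout, at embryonic day E18.5. Both arrays held the same 1152 spots, of which 3 for each of 377 probes entered the comparison. The arrays measure miRNA, so the Esr1 transcript itself was not measured and the genotype labels were not checked against it. No replicate array stands behind any value, and the SD beside a probe's intensity is over its 3 spots on 1 array.

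Most probes lay close to the lowest intensity of their array. The lowest spot was 98.1 units on the wild type array and 98.9 units on the knockout array, and the median probe was 1.39 and 1.69 times as bright as that. The median probe intensity was 136 units for wild type and 167 units for knockout. On the wild type array 349 of the 377 probes had a mean under 200 units, and on the knockout array 281 did. The brightest of the 377 probes reached 558 units on the wild type array and 983 units on the knockout array. The 5 brightest probes of the 2 arrays had 2 probes in common. Neighbouring spots of a probe had a median coefficient of variation of 5.78% on the wild type array and 6.21% on the knockout array.

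The comparison of knockout with wild type asked which miRNAs differ in embryos that lack ERalpha. Among the 188 brighter probes, 0 were at least 2-fold higher and 0 were at least 2-fold lower on the knockout array after quantile normalisation. At 1.5-fold, 10 probes were higher and 1 was lower. The largest difference upward was 1.75-fold and the largest downward was 1.57-fold. Differences had a median of -0.03 on the log2 scale, an SD across probes of 0.33 and quartiles of -0.26 and 0.30. The knockout value was the higher for 86 of the 188 probes and the lower for 101. Across these probes, which are not independent replicates, Pearson's r between the arrays was 0.66 and Spearman's rho was 0.27. Across all 377 probes r was 0.76 and rho was 0.63. Quantile normalisation gives both arrays the same set of values. The brightest probe, the same on both arrays, had 983 units on the knockout array and 558 units on the wild type array. Its log2 difference was 0.81 without scaling and 0 after quantile normalisation. The count of probes at least 2-fold higher depended on the scaling, at 11 with no scaling and 0 with loess. The count at least 2-fold lower was 0 in both.

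After quantile normalisation, the probes with the largest differences upward among the 188 brighter probes were PS20277 and PS20333. Without scaling, 5 of the 377 probes lay above PS20277, among them PS20333. PS20277 had an intensity of 363 ± 25.2 units (SD of 3 spots) on the knockout array and 149 ± 13.2 units on the wild type array, a log2 difference of 0.80 after quantile normalisation and 1.29 without scaling. PS20333 had 745 ± 74.7 units on the knockout array and 241 ± 17.1 units on the wild type array, a log2 difference of 0.79 after quantile normalisation and 1.62 without scaling. Both stayed above 0 in every alternative setting that was run. The 12 largest differences upward were all at least 0.56.

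The probes with the largest differences downward after quantile normalisation were PS20454 and PS20432. Both were below 0 in every setting that scaled the arrays, at -0.20 and -0.20 in the authors' deposited value table and -0.29 and -0.30 with median centring. Both were above 0 with no scaling, where the median of the 188 probes brightest in that setting was 0.43. PS20454 had an intensity of 320 ± 16.5 units on the knockout array and 302 ± 1.24 units on the wild type array, so that its log2 difference was -0.65 after quantile normalisation and 0.08 without scaling. PS20432 had 271 ± 26.4 units on the knockout array and 256 ± 12.4 units on the wild type array, with log2 differences of -0.58 and 0.08. The 12 largest differences downward were all at or below -0.40.

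Without scaling, the median difference over all 377 probes was 0.19, against -0.04 after quantile normalisation. At least 2-fold, 11 of the 377 probes were then higher on the knockout array and 0 were lower. In the authors' deposited value table, 6 of the 188 probes brightest in that table were at least 2-fold higher and 0 were lower. In each of these probe counts the difference is relative to the scaling used, and the unsubtracted lowest level of the arrays makes a fold smaller than the fold above that level.

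**Figure D1:**
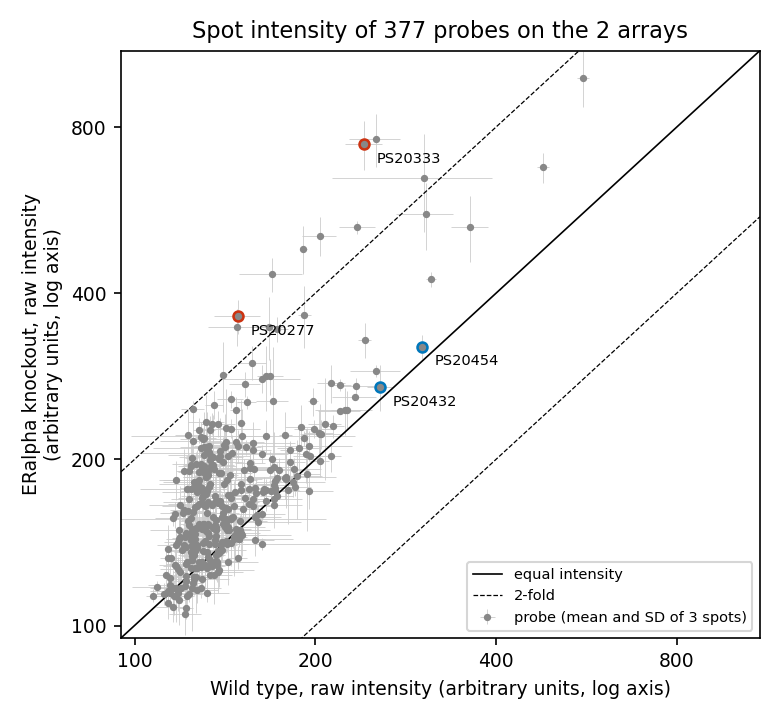
Raw intensity of each of the 377 probes on the wild type array (x axis) and the ERalpha knockout array (y axis), in arbitrary units on log axes, with points at the mean and bars at the SD of 3 spots. The solid line marks equal intensity and the dashed lines 2-fold. PS20277 and PS20333 lie above the upper dashed line, and PS20454 and PS20432 lie close to the line of equal intensity.

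The differences followed the order of the probes in the files. Of the variance of the differences over the 377 probes, 59.3% lay between the 16 segments, and the highest share in 1000 random orders was 10.3%. Without scaling, 47.7% lay between segments. The median unscaled difference was -0.01 in segments 1 to 4, 0.40 in segments 5 to 8, 0.11 in segments 9 to 12 and 0.50 in segments 13 to 16. Between probes in the first and the last of the 6 columns, it went from 0.17 to 0.59 in segments 5 to 8 and from 0.21 to 0.60 in segments 13 to 16. In segments 9 to 12 it ran the other way, from 0.24 to 0.09, and in segments 1 to 4 it went from 0.02 to 0.08. The 12 largest differences upward after quantile normalisation all lay in segments 5 to 8 and 13 to 16, and the 12 largest downward all lay in segments 1 to 4 and 9 to 12. Of the 93 brighter probes in segments 5 to 8 and 13 to 16, 83 were above 0, against 3 of the 95 brighter probes in the other segments.

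Since 0 of the 188 brighter probes were at least 2-fold higher or lower after quantile normalisation, the same holds within each block of 4 segments. The median difference of the brighter probes was -0.17 in segments 1 to 4 and 0.24 in segments 5 to 8. It was -0.26 in segments 9 to 12 and 0.32 in segments 13 to 16. In the same order, the brighter probes numbered 19 of 94, 43 of 96, 76 of 91 and 50 of 96. The filter on brightness therefore also followed the order of the probes. After the medians of segments and columns were removed from the unscaled differences, 2 probes were at least 2-fold higher and 0 were lower. PS20333 was 1 of the 2, at 1.38, and the other was a probe at 1.14 that is not among those named, while PS20277 was at 0.76, PS20432 at -0.13 and PS20454 at 0.

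The 3 knockout spots lay wholly above or wholly below the 3 wild type spots for 51.2% of the 377 probes after quantile normalisation, against 10% by chance for 3 spots against 3. They were above for 82 probes and below for 111. This compares the spots of 2 arrays, with their positions, and not the genotypes.

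**Figure D2:**
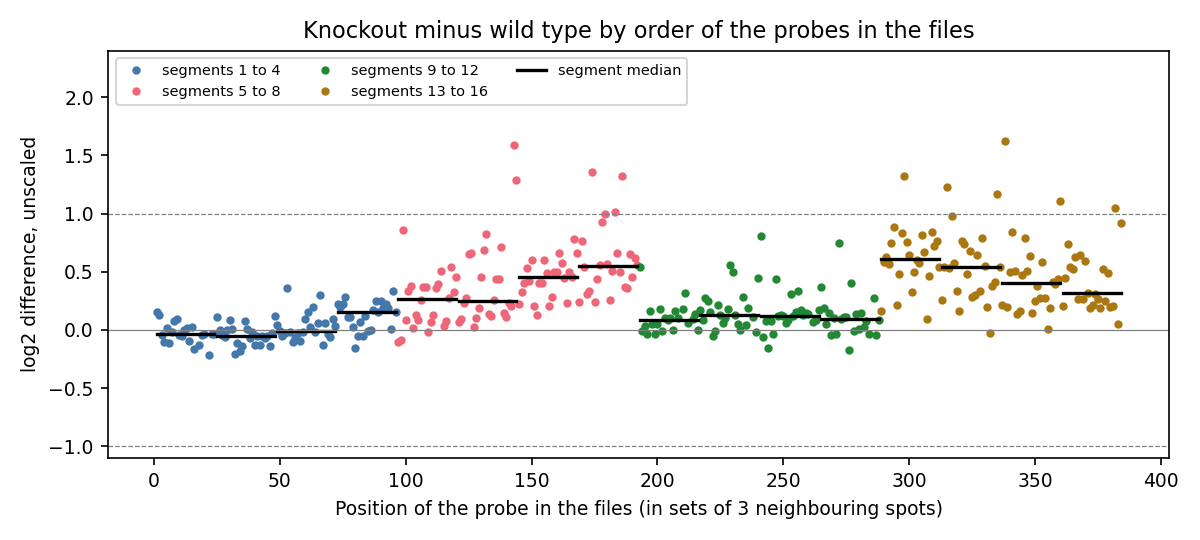
Unscaled log2 difference, knockout minus wild type, of each of the 377 probes (points, y axis) against the place of the probe in the files (x axis), coloured by blocks of 4 segments. Black lines are segment medians, which lie near 0 in segments 1 to 3 and at 0.61 in segment 13, and dashed lines mark 2-fold.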

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

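The tests of position on the 11 brighter probes and of the probe printed 12 times across segments were chosen after the result was seen, as were the choice of those 11 probes as a set and the summary of their ratios by a median. The tests of the slope within probes, of single spots and of the ratio above the local level were set out before.

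The probe printed 12 times, which is outside the comparison, stood out as a signal in data not otherwise used. It was 2.14 times as bright on the knockout array as on the wild type array, at 14765 ± 1157 units against 6896 ± 476 units (SD of 12 spots). After the authors' factors the ratio was 1.76. Its unscaled log2 difference was 1.29, 1.19, 1.01 and 0.90 in segments 9, 10, 11 and 12.

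Differences that follow the order of the probes were weighed first, and both explanations stay open. For uneven background or hybridisation, the test set out beforehand asked whether the 3 neighbouring spots of a probe show the trend of segments 5 to 8. The slope within probes, times 3, was -0.070 with a standard error of 0.038, against 0.11 between neighbouring probes. The outcome named for this explanation was not seen, and the outcome named against it, a slope within 2 standard errors of 0, was. The files do not give the direction in which the 3 spots of a probe run, so this slope cannot be read for or against a gradient. The probe printed 12 times went from 1.29 in segment 9 to 0.90 in segment 12, a range of 0.40 against a mean SD of 0.12 within segments. The difference of 1 probe thus varied with its place. This was the outcome named against the explanation that miRNAs printed in the same part of the array change together. The medians of the other probes in those segments varied by 0.04, so this 1 probe does not decide whether probes printed together belong to miRNAs that change together, and no names are at hand.

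The second pattern is 11 probes at least 2-fold brighter on the knockout array without scaling, all of them in segments 5 to 8 and 13 to 16. Removing segment and column medians lowered their median difference from 1.29 to 0.66 and left 2 above 2-fold. These medians also hold the overall difference between the arrays, a median of 0.19 over all 377 probes, so the fall cannot be credited to position alone. The largest was still 1.38 and the lowest 0.47, above 3 robust SDs of all residuals (0.31). This was the outcome named against position, but probes picked for a large difference exceed the medians of their neighbours in part by that choice. How large that part is was not tested. The difference of the probe printed 12 times varied by 0.40 over segments 9 to 12, where medians of the other probes varied by 0.04. Such medians can miss variation with place. That probe was far brighter than the 11, at 6896 units on the wild type array, and segments 9 to 12 hold none of them. Whether medians miss as much near the 11 was not tested, so position as the whole cause stays open. A single aberrant spot is argued against for 10 of the 11, whose dimmest knockout spot was at least 1.5 times the brightest wild type spot (1.35 times for the other one). Brighter labelling or scanning of the knockout array stays open: over the 7 probes clearly above their segment on the wild type array, the ratio above the local level was 3.32 to 12.6, with a median of 4.85 and a standard error of 1.48, less than 2 standard errors above the 2.14 of the probe printed 12 times, and probes picked for a high ratio would lie above it in part by that choice. With 1 array per genotype, ERalpha genotype cannot be told apart from any other difference between the 2 RNA samples.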

How the results depend on the processing

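The removal of position, normexp, the subtraction of the lowest spot and the median of the 3 spots were chosen after seeing the data. The other settings were chosen before. Where a setting changed the intensities, its 188 brighter probes were chosen anew. Shifts of the counts and of the median can therefore mix the setting with a change of probes. The number of probes at least 2-fold higher, 0 after quantile normalisation, was 11 with no scaling, 2 with median centring, 2 with 75th percentile scaling, 6 in the authors' value table, 3 with normexp, 20 with each array's lowest spot subtracted and 2 with segment and column medians removed without scaling. At a 1.5-fold threshold 10 were higher and 1 was lower. The number at least 2-fold lower, 0, was 3 with the lowest spot subtracted. In the other settings both counts stayed at 0. The median difference, -0.03, was 0.43 with no scaling, 0.054 with median centring, 0.062 with 75th percentile scaling, 0.022 with loess, 0.13 in the value table, -0.13 above the 75th percentile of brightness, -0.083 for probes above the median on both arrays and -0.11 with the lowest spot subtracted. With segment medians removed it was 0.023, with segment and column medians removed 0.00043, and 0.026 when this was done without scaling, where centring sets it near 0. With no scaling it keeps the overall difference between the arrays, a median of 0.19 over all 377 probes. For the others the cause was not tested. PS20277 and PS20333 were above 0 in all 13 alternatives, between 0.55 and 1.46 and between 0.60 and 1.62. PS20454 and PS20432 were above 0 in 1 of 13 each, with no scaling. The share of variance between segments lay between 47.4% and 61.8% over 10 alternatives. An offset of 0 is the setting used. Another background column, the brightest probe per miRNA and all alternatives of the miRNA lists and shared transcripts were not run. No replicate could be left out. No paired analysis was possible because each group has 1 array. Signal near the lowest level of the arrays limits every fold.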

Other observations

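After removal of segment and column medians from the unscaled differences, 24 probes lay more than 3 robust SDs above 0 and 6 lay more than 3 robust SDs below. These counts were looked at after the data were seen. Of the 24 probes, 17 lay in segments 5 to 8 and 13 to 16, as did all 6 of those below. Among the 20 brightest probes of the wild type array, 9 were among the 24. The brightness of the probes on both arrays also followed the order in the files: 34.4% of the variance of log2 intensity lay between segments on the wild type array and 27.3% on the knockout array.

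PS20454 and PS20432, bright on both arrays, had ratios above the median of their segment of 1.09 and 1.09, knockout over wild type. Both lie in segment 12, where the probe printed 12 times had a ratio of 1.86, against 2.14 over its 4 segments.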
